A study of Homo sapiens with 50 samples.

How the data were processed

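RNA was taken, per the labels' protocols, from sections of formalin-fixed, paraffin-embedded skin biopsies, copied into complementary DNA, labelled with biotin and measured on 50 microarrays. The condition labels put 21 arrays in lichen planus (LP), 17 in hypertrophic LP (HLP) and 12 in a condition given only as an abbreviation. That condition was read as healthy controls, because the series design names these 3 groups and no other. The labels name no batch and do not say that each array came from a separate donor, so p-values measure only the spread between these samples, which may in part be technical.

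The authors deposited 1 table of expression values, read here as log2 values, that were made with RMA before deposit, per the submitters' processing notes. Its version is not given in the sources used here. RMA, as commonly run, corrects background, normalizes by quantiles and sums the probes of a set on the log2 scale. The log base and any centring are not stated for the deposited table. Its values ran from -1.188 to 12.439, and since the highest value exceeds 11.09, the natural log of the scanner's 16-bit maximum, they were read as log2 values. Array medians ran from 0.7195 to 0.9213, so the deposited arrays do not share 1 distribution. The values were used as deposited, so a difference of 1 is read as a 2-fold change under that reading of the scale, and RMA compresses differences of dim probe sets.

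The table held 53617 probe sets. The platform annotation used here pairs 23871 of them with 1 gene symbol, 1842 with several and leaves 27904 unnamed. Symbols were updated through gene identifiers for 22569 probe sets, through the symbol for 733 and through an older synonym for 565, with 4 kept as given, and the update changed 655 symbols. Probe sets of the Y chromosome and of the X inactivation genes, 46 in all, were left out because the donors are human. For each of the 662 genes with several probe sets the set with the highest mean over all arrays was taken, which left 22312 genes. Genes were identified by symbol, and no coordinates are given because the annotation used names no genome build for the probe sets.

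All 3 groups entered 1 linear model per gene in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 1 mean per group, no covariate), and p-values of each comparison were adjusted by Benjamini-Hochberg over the 22312 genes. A gene was called at an adjusted p under 0.05, and a second count took those that also differed at least 2-fold. Values after ± are standard errors from this model unless SD is written. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 40 lists of a comparison, with an estimated correlation and with fry as alternatives. The camera test sets a list against all other genes, so a list that does not pass may still differ between the groups. For the same reason its direction can differ in sign from the list mean. The fry test takes each list by itself. The lists were 20 pathways and 20 cell types of skin, with 646 entries of which 581 were measured. Some lists share genes, and 12 of the 28 measured genes of the interferon-gamma list also stand in another list.

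Genes are named by a rule. It took in each comparison the 8 highest and 8 lowest log2 changes among called genes, passing over long intergenic and small RNA, microRNA, olfactory receptor, locus and open reading frame symbols. It then took up to 3 called members of each list with the largest change, or the member with the lowest p where none was called, and 24 preset genes, of which 22 were measured. KRT6A had no probe set with 1 gene name, and 1 other preset gene is not reported here. The rule gave 165 genes. Genes outside it that are named were chosen after their values were seen, and the text says so there.

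The groups, the main fit, the lists, the naming rule, and most alternatives were fixed before the data were examined. These alternatives left out dim genes, averaged probe sets, used a mean-variance trend, array weights, the rank-sum test or only the groups compared, normalized by quantiles again, centred arrays on their medians, or left out the least correlated array of each group. Others took runs of sample numbering as a covariate or within themselves. These 3 runs, called title blocks here, stand in for processing order, although no label calls them a batch. Chosen after the data were seen were the alternatives on signal range (the 95th percentile of each array as a covariate, or only arrays in the range that lesions and controls share) and the refits without each of the 50 arrays in turn.

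The shared control arrays were handled with 100 simulated draws of unchanged groups and 100 random splits of the controls into 6 and 6. Correlations across arrays used permutation tests with 100000 resamples, 2-sided. Array figures, scores and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The model was tested on simulated data of 22312 genes with 50 genes changed at each size. The simulated noise was normal, independent between genes and arrays, and of the same spread per gene in all groups. It held no array-wide difference in signal range, so the shares below do not give the power in the real data. In the LP and control comparison it recovered 34% of genes changed by 0.5 log2 units, 92% at 1, 100% at 1.5 and 98% at 2. In the HLP and control comparison these shares were 34%, 90%, 96% and 100%, and in the HLP and LP comparison 50%, 98%, 100% and 100%. Of the genes simulated as unchanged 6, 8 and 6 were called in these comparisons. The number of arrays limits the precision of each value. No array pair held the same values.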

Results

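Skin biopsies were profiled on 50 arrays to ask which genes are regulated in lichen planus lesions. Lichen planus (LP) is an inflammatory skin disease in which lymphocytes gather under the epidermis and injure its basal cells, and hypertrophic LP (HLP) is a form with thick plaques. There were 21 LP, 17 HLP and 12 healthy control arrays. Expression of 22312 genes was compared between LP and control, HLP and control, and HLP and LP. The number of arrays limits the precision of each value.

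The arrays of the lesions had a wider range of signal than those of the controls. The 95th percentile of an array averaged 3.81 ± 0.19 (SD, n = 21) in LP, 3.83 ± 0.19 (SD, n = 17) in HLP and 3.48 ± 0.15 (SD, n = 12) in control. The mean correlation of an array with others of its group was 0.828 in LP, 0.830 in HLP and 0.676 in control. This range differed between groups as the gene lists did, so the number of members called with it as a covariate is given beside each list that passed against control. The percentile comes from the same expression values, so the covariate can also remove real differences.

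**Figure D1:**
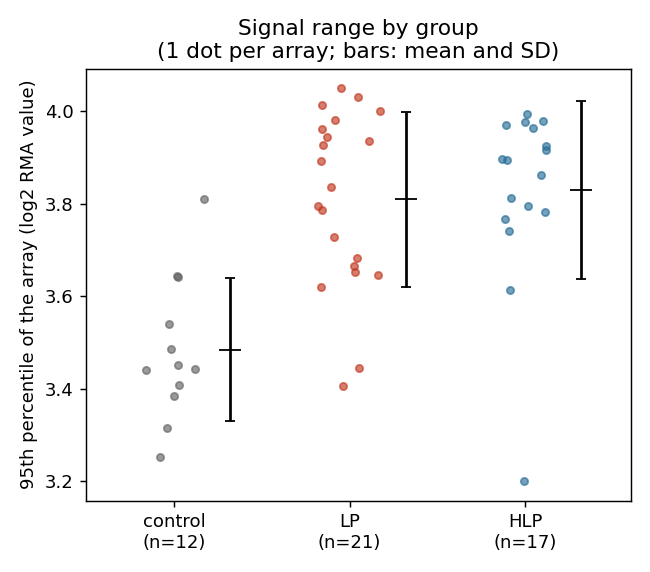
The 95th percentile of each array (vertical axis, log2 RMA value) is plotted by group for 12 control, 21 LP and 17 HLP arrays, 1 dot per array with the mean and SD as bars. Control arrays averaged 3.48, below LP at 3.81 and HLP at 3.83.

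In LP, chemokines that draw T cells into tissue, antigen presentation genes and genes of wounded epidermis stood far above healthy skin. CXCL9, a chemokine induced by interferon-gamma, was higher by a log2 difference of 6.79 ± 0.31 (21 LP against 12 control arrays, adjusted p = 2.5e-24), and all 21 LP arrays lay above every control. Its control mean of 1.59 lay close to the control arrays' mean median of 0.862, where RMA compresses differences, so no fold is given. For the same reason the log2 differences of CXCL9 against control, in LP and in HLP, are uncertain in size. CXCL10, which binds the same receptor, was higher by 5.45 ± 0.39 (adjusted p = 2.57e-16). S100A9, a subunit of calprotectin, was higher by 6.04 ± 0.37 and exceeded every control in 18 of 21 arrays. The cornified envelope gene LCE3D was higher by 5.37 ± 0.33, and HLA-DRA, the alpha chain of HLA-DR, by 3.82 ± 0.23. Both exceeded every control in 21 of 21 arrays.

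Of the 22312 genes, 7104 changed in LP, 4794 higher and 2310 lower (67.5% higher). At least 2-fold changes were 1574, with 1397 higher and 177 lower (88.8% higher). After the arrays were normalized by quantiles again, 6225 genes changed, 3279 higher and 2946 lower (52.7% higher), and the 2-fold changes were 618 higher and 447 lower (58.0% higher). With signal range as a covariate 1764 genes were called, of which 1658 were among the 7104.

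The interferon and antigen presentation lists rose in LP. In each list the count over all genes is followed by the count adjusted over the list alone. Of 30 interferon-stimulated genes 21 rose over all genes and 24 adjusted over the list alone, with IFI44 higher by 3.17 ± 0.28 and the RNA sensor IFIH1 by 2.23. The list's mean log2 difference was 1.07 (camera adjusted p = 4.2e-11), its call was lost at adjusted p = 0.0787 with an estimated correlation, and 17 members were called higher with the range covariate. In the interferon-gamma response list 21 of 28 rose, 23 adjusted over the list alone and 13 with the range covariate, and the mean was 1.34 (adjusted p = 2.85e-12). GBP5, a guanylate-binding protein, was higher there by 2.93 ± 0.29, and CXCL11 by 2.33. Among 15 genes of MHC class I presentation 14 rose, 15 adjusted over the list alone and 9 with the covariate (mean 1.10, adjusted p = 2.67e-10). They included B2M, the class I light chain, at 2.74 ± 0.23, HLA-E at 2.21 and the proteasome activator PSME2 at 1.55. Of 12 class II genes 8 rose, while adjusted over the list alone 9 rose and 1 fell, and 7 were higher with the covariate (mean 1.21, adjusted p = 1.62e-08). CTSS, the protease that trims the invariant chain, was higher by 2.61 ± 0.16 (adjusted p = 1.07e-18), and CD74, the invariant chain itself, by 1.55. JAK-STAT components rose in 9 of 16 genes by both counts and in 6 with the covariate (mean 0.63, adjusted p = 0.000219). Among them were JAK2, which signals from the interferon-gamma receptor, at 1.40 ± 0.22 and the interferon receptor gene IFNAR1 at 1.71. IFNG itself gave 0.52 ± 0.24 (adjusted p = 0.0913), and 0.64 (adjusted p = 0.0389) without control replicate 3. IDO1 gave 0.37 (adjusted p = 0.0828), 0.41 (adjusted p = 0.0497) without LP replicate 20 and 0.43 (adjusted p = 0.0495) without control replicate 5.

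Lymphocyte and myeloid genes rose with them. Of 19 lymphocyte chemokines and receptors 14 rose by both counts, all genes and adjusted over the list alone, and 12 with the covariate (mean 1.49, adjusted p = 1.14e-08). CCR4, a receptor of skin-homing T cells, was higher by 2.50 ± 0.30 and CCL19, a ligand of CCR7, by 1.18. Of 14 cytotoxic granule genes 7 rose by both counts and 5 with the covariate (mean 0.81, adjusted p = 0.000633). Granzyme A (GZMA) was higher by 2.50 ± 0.30, with 21 of 21 arrays above every control, granzyme K (GZMK) by 2.03 and GZMB by 0.48 (adjusted p = 0.0118). GZMA in the control arrays ran from 0.463 to 1.58, close to their mean median of 0.862. As for CXCL9, the size of its differences against control, in LP and in HLP, is therefore uncertain. PRF1, which encodes perforin, gave 0.07 (adjusted p = 0.738). T cell genes rose in 6 of 11 by both counts and in 6 with the covariate (mean 0.81, adjusted p = 0.000779). They included CD2 at 2.22 ± 0.20 and CD3D, part of the T cell receptor complex, at 2.01 ± 0.22. The list of CD4 helper and regulatory T cells had 6 of 8 higher by both counts and 5 with the covariate (mean 0.83, adjusted p = 0.000633). Among them was ICOS at 0.92. Immune checkpoints rose in 9 of 14, 11 adjusted over the list alone and 5 with the covariate (mean 0.67, adjusted p = 0.000321), led by CD96 at 2.06 and CD86 at 1.38. Macrophage and monocyte genes rose in 10 of 14 by both counts and in 8 with the covariate (mean 0.91, adjusted p = 6.9e-08). They included TYROBP, a signalling adaptor of myeloid receptors, at 2.25 and CD68 at 2.06 ± 0.15. Conventional and mature dendritic cell genes rose in 9 of 12 by both counts and in 7 with the covariate (mean 0.65, adjusted p = 0.000633). Among them were the maturation markers LAMP3 at 1.39 and CD83 at 0.95. Plasmacytoid dendritic cell genes rose in 5 of 9 by both counts and in 3 with the covariate (mean 0.51, adjusted p = 0.0207, adjusted p = 0.114 with an estimated correlation). They included TLR7 at 1.07. The list of CD8 T and NK cells did not pass camera (mean 0.48, adjusted p = 0.263), but passed fry as higher (adjusted p = 0.00246). It had 3 members higher and 1 lower by both counts, and CD8A gave 0.08 (adjusted p = 0.748).

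Epidermal genes of wounding, cornification and adhesion were higher in LP. Wound and hyperproliferation genes rose in 10 of 14 by both counts and in 7 with the covariate (mean 2.04, adjusted p = 9.07e-10). Among them were the protease inhibitor PI3 at 5.26 ± 0.43, SERPINB3 at 4.33 ± 0.33 and KRT16, a keratin of injured epidermis, at 3.11 ± 0.27. The cornified envelope list had 20 of 28 higher and 1 lower over all genes, 22 higher and 1 lower adjusted over the list alone, and 9 higher and 1 lower with the covariate. Its mean was 1.54 (adjusted p = 2.08e-11), with adjusted p = 0.052 with an estimated correlation. LCE3E was higher there by 3.44 and LCE2D by 3.28, while KRT77, a keratin of sweat ducts, was lower at -0.84. LORICRIN gave -0.06 (adjusted p = 0.765). Desmosome and adhesion genes rose in 9 of 15, 11 adjusted over the list alone and 5 with the covariate (mean 1.03, adjusted p = 4.71e-05, adjusted p = 0.122 with an estimated correlation). They included DSG3, a desmosomal cadherin of the lower epidermis, at 2.96 ± 0.32 and DSC2 at 2.53. Basal keratin and attachment genes rose in 6 of 12 over all genes, in 6 with 1 lower adjusted over the list alone, and in 2 with the covariate. KRT14, a keratin of the basal layer, was higher by 1.09 and its partner KRT5 by 1.02 ± 0.19. That list's mean of 0.49 (adjusted p = 0.0342, adjusted p = 0.256 with an estimated correlation) lost its call without control replicate 3 (0.47, adjusted p = 0.0538) or control replicate 11 (0.46, adjusted p = 0.0576). KRT15 gave -0.40 (adjusted p = 0.0791), and passed without LP replicate 14 (-0.44, adjusted p = 0.0469), control replicate 10 (-0.49, adjusted p = 0.0304) or control replicate 11 (-0.49, adjusted p = 0.0293). Cell cycle genes rose in 13 of 25 by both counts and in 2 with the covariate (mean 0.46, adjusted p = 0.0021, adjusted p = 0.198 with an estimated correlation). Among them were TOP2A at 1.36 ± 0.20 and MKI67, a marker of dividing cells, at 0.96 ± 0.20. Cell death genes rose in 11 of 21 by both counts and in 4 with the covariate (mean 0.42, adjusted p = 0.00401, adjusted p = 0.082 with an estimated correlation). They included TNFSF10, the death ligand TRAIL, at 1.57 and CASP4 at 1.46. Immediate-early genes rose in 6 of 16, 8 adjusted over the list alone and 3 with the covariate (mean 0.50, adjusted p = 0.00401, adjusted p = 0.211 with an estimated correlation). Among them was ZFP36 at 1.76.

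In the dermis lists, extracellular matrix genes rose in 14 of 26 over all genes, in 16 with 1 lower adjusted over the list alone, and in 5 with the covariate (mean 0.73, adjusted p = 6.56e-05, adjusted p = 0.114 with an estimated correlation). They included COL6A3 at 2.23 ± 0.24 and tenascin C (TNC) at 1.92. Fibroblast genes rose in 6 of 12 by both counts and in 2 with the covariate (mean 0.89, adjusted p = 0.00257, adjusted p = 0.256 with an estimated correlation). Among them was the proteoglycan LUM at 2.95 ± 0.29. The sebaceous gland list was the 1 list that fell, with 6 of 12 lower over all genes, 7 adjusted over the list alone and 4 with the covariate. Its mean log2 difference was -0.43 (adjusted p = 0.00401, adjusted p = 0.211 with an estimated correlation), and -0.26 (adjusted p = 0.0267) without control replicate 7. AWAT2, which makes wax esters of sebum, was lower at -0.90 ± 0.20 (adjusted p = 0.000316), below the control median in 21 of 21 arrays. It stood at 4.35 in control replicate 7, which raises the control mean, against 0.449 to 2.22 in the other controls. Its means in LP and HLP lay below the mean array medians of those groups (0.782 and 0.777), so the floor may limit the size of its fall.

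Other lists did not pass camera in LP. The IL-17 and IL-36 response had 6 higher and 4 lower of 24 by both counts, with a mean of 0.67 but a median of -0.09 (adjusted p = 0.678). Its members S100A7, S100A8 and S100A12, antimicrobial proteins of inflamed epidermis, were higher by 5.18 ± 0.49, 4.17 ± 0.33 and 1.97. With the range covariate 3 of its members were called higher and 0 lower. IL17A gave -0.23 (adjusted p = 0.129), with -0.28 (adjusted p = 0.0444) without LP replicate 3, and IL36G gave 0.37 (adjusted p = 0.191). The type 2 response had 5 of 16 higher, 6 adjusted over the list alone (mean 0.35, adjusted p = 0.349). It passed with the covariate at adjusted p = 0.012, and its member IL13RA1, a subunit of the IL-13 receptor, was higher by 1.90. Lipid synthesis had 5 higher and 3 lower of 20 (5 and 4 adjusted over the list alone, mean 0.20, adjusted p = 0.731). ABCA12, a lipid transporter of the skin barrier, was higher by 1.80. Langerhans cells had 3 of 5 higher (4 adjusted over the list alone, mean 0.54, adjusted p = 0.164). Mast cells had 3 of 7 higher (3 higher and 1 lower adjusted over the list alone, mean 0.46, adjusted p = 0.248), ribosomal proteins 3 of 11 (mean 0.32, adjusted p = 0.228) and melanocytes 2 of 9 (mean 0.34, adjusted p = 0.434). Sweat glands had 2 of 13 lower (1 adjusted over the list alone, mean -0.17, adjusted p = 0.104) and passed with the covariate at adjusted p = 0.0102. The covariate left 3 members called higher in the type 2 list, 2 in the Langerhans list and 0 in the mast cell, ribosomal and melanocyte lists, and 2 lower in each of the lipid and sweat gland lists. In the shared signal range the sweat gland (-0.29, adjusted p = 0.0362), hair follicle (-0.16, adjusted p = 0.0499) and Langerhans lists (0.55, adjusted p = 0.0499) passed. Adipocytes gave a mean of -0.03 (adjusted p = 0.427). Mean and test differed in sign for B cells (mean 0.18, adjusted p = 0.872), neutrophils (0.25, 0.997), endothelial cells (0.06, 0.731), smooth muscle (0.09, 0.993), skeletal muscle (0.07, 0.817), hair follicle (0.05, 0.503) and nerve (0.09, 0.855). Medians of the endothelial (-0.03), skeletal muscle (-0.08) and nerve (-0.03) lists had the sign of the test.

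The genes that fell most in LP were largely small RNAs and pseudogenes. USP17L15, of a repeated deubiquitinase family, was lower at -3.69 ± 0.35 (adjusted p = 5.75e-12, below every control in 19 of 21 arrays), and EDC4, a scaffold of mRNA decapping, at -2.63 ± 0.27 (adjusted p = 3.2e-11, below every control in 15). The Y RNA pseudogene RNY1P4 was lower at -2.72 ± 0.52, and CXADRP2 at -2.11. Of the 177 genes at least 2-fold lower, 70 were small RNAs (39.5%, against 5.7% of tested genes), 55 pseudogenes (31.1%, against 6.8%) and 37 protein coding (20.9%, against 76.4%). Genes with near-identical copies can share probe signal, so USP17L15 and the pseudogenes are uncertain as single genes. Of all lower calls in LP 68.4% were genes below the median brightness, against 5.9% of higher calls, but of the 177 genes at least 2-fold lower 19.8% were.

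In LP the range covariate lowered the count of calls from 7104 to 1764, and the 10 LP and 12 control arrays within a shared range gave 2533. In the narrow part of that range, with 8 LP and 3 control arrays, the fibroblast mean was -0.13 and the basal mean -0.0125, and the covariate ended the basal call. That narrow part kept 18 of the 23 list calls, losing the basal, desmosome, matrix, plasmacytoid dendritic cell and fibroblast lists. Title block 1, with 21 LP and 4 control arrays, gave 4031 calls and 19 of the 23 called lists, losing the basal, cell death, plasmacytoid dendritic cell and sebaceous lists, and with title block as a covariate the plasmacytoid list alone was lost. Without dim genes 14 lists passed, the cytotoxic, basal, cell cycle, cell death, immediate-early, CD4, both dendritic cell and fibroblast lists losing their calls, and repeated quantile normalization ended those of the basal and immediate-early lists.

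**Figure D2:**
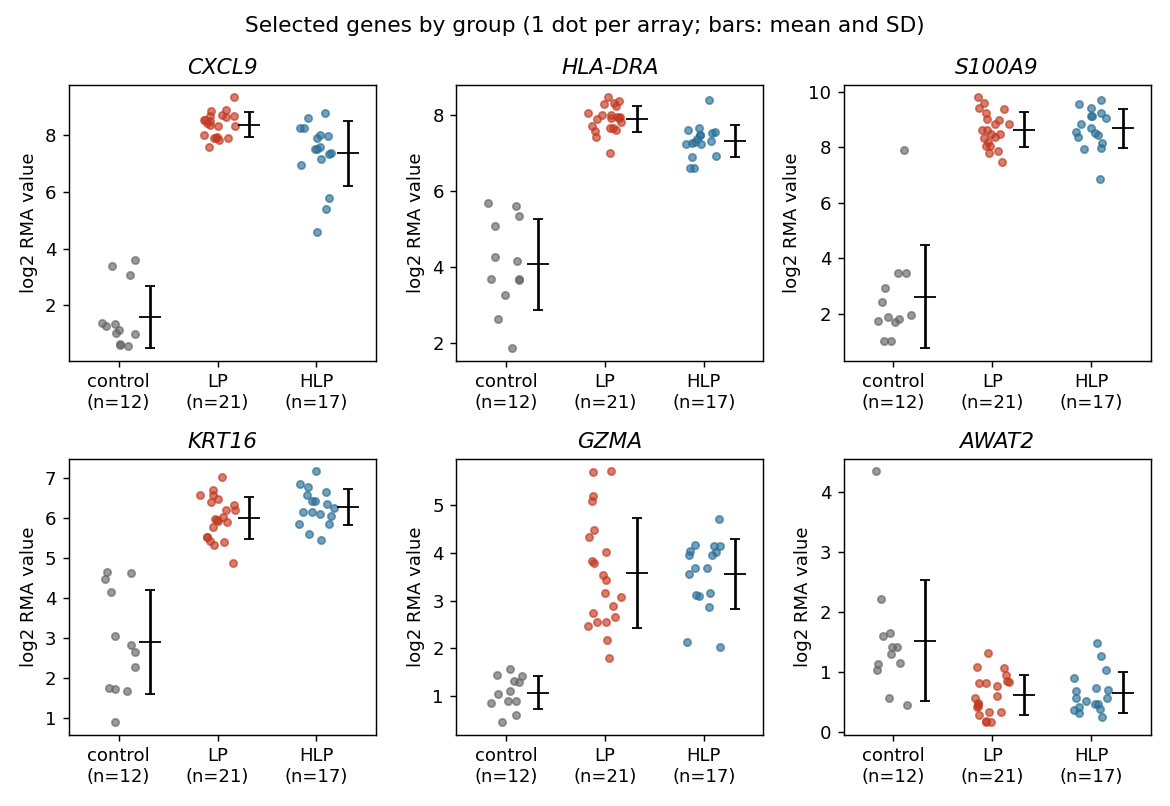
Expression (vertical axes, log2 RMA value) of CXCL9, HLA-DRA, S100A9, KRT16, GZMA and AWAT2 in 12 control, 21 LP and 17 HLP arrays, 1 dot per array with the mean and SD as bars. CXCL9 averaged 1.59 in control, 8.38 in LP and 7.36 in HLP, and AWAT2 averaged 1.53, 0.62 and 0.66.

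In HLP, single genes of calprotectin, the late cornified envelope and the chemokines stood far above healthy skin. S100A9 was higher by a log2 difference of 6.08 ± 0.38 (17 HLP against 12 control arrays, adjusted p = 3.49e-18), LCE3D by 5.93 ± 0.34 (adjusted p = 1.45e-19) and CXCL9 by 5.77 ± 0.32 (adjusted p = 3.99e-20), the latter 2 above every control in 17 of 17 arrays. The antimicrobial protein gene S100A7 was higher by 5.28, and SERPINB3 by 4.48. POSTN, periostin of the dermal matrix, was higher by 2.85 ± 0.49 (adjusted p = 1.04e-05), but gave -0.51 in the narrow part of the shared signal range, with 5 HLP and 3 control arrays.

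HLP had 6541 changed genes, 4323 higher and 2218 lower (66.1% higher), and 1470 at least 2-fold, 1304 higher and 166 lower (88.7% higher). Quantile normalization again gave 5820, 3123 higher and 2697 lower (53.7% higher), with 594 higher and 437 lower at 2-fold (57.6% higher). The range covariate left 1259 calls, of which 1158 were among the 6541. Within title block 1, with 6 HLP and 4 control arrays, limma called 2296 genes, and within blocks 2 and 3, with 11 HLP and 8 control arrays, 3767. With title block as a covariate it called 6536. Of the 20 lists called in HLP 12 passed in title block 1, which lost the cytotoxic, basal, cell cycle, cell death, checkpoint, T cell, CD4 and sebaceous lists. Without dim genes 12 of the 20 passed, the cytotoxic, JAK-STAT, basal, cell cycle, cell death, checkpoint, T cell and CD4 lists losing their calls. Array weights ended those of the cytotoxic, checkpoint and T cell lists, repeated quantile normalization that of the basal list, and title block as a covariate, or leaving out the least correlated arrays, that of the checkpoints. The narrow part of the shared range kept 14 of the 20, losing the cornified envelope, basal, desmosome, cell cycle, matrix and fibroblast lists.

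Epidermal lists rose in HLP. Wound genes rose in 11 of 14 over all genes and adjusted over the list alone, and in 7 with the range covariate (mean 2.17, adjusted p = 1.59e-11). They included SPRR1A, a cornified envelope precursor, at 4.21 and KRT16 at 3.38 ± 0.28. The cornified envelope list had 23 of 28 higher and 1 lower, 25 and 1 adjusted over the list alone, 10 and 1 with the covariate (mean 1.74, adjusted p = 6.23e-15, adjusted p = 0.0614 with an estimated correlation). Among them were LCE3E at 4.30 ± 0.34 and LCE2D at 3.59. Desmosome genes rose in 9 of 15, 10 adjusted over the list alone and 5 with the covariate (mean 1.19, adjusted p = 1.5e-06, adjusted p = 0.114 with an estimated correlation). They included DSG3 at 3.35, DSC2 at 2.87 and DSC1 at 2.29. Basal genes rose in 6 of 12 by both counts and in 2 with the covariate (mean 0.53, adjusted p = 0.0194, adjusted p = 0.225 with an estimated correlation). Among them was KRT5 at 1.39. Cell cycle genes had 13 of 25 higher and 1 lower, 13 and 2 adjusted over the list alone, and 0 with the covariate (mean 0.39, adjusted p = 0.012, adjusted p = 0.262 with an estimated correlation). They included TOP2A at 1.14 and MKI67 at 0.66. This list and the basal list lost their calls with the range covariate. Cell death genes rose in 7 of 21 by both counts and in 3 with the covariate (mean 0.39, adjusted p = 0.0168, adjusted p = 0.163 with an estimated correlation). Among them were CASP4 at 1.72 and TNFSF10 at 1.69.

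Interferon and presentation lists rose in HLP as well. Interferon-stimulated genes rose in 21 of 30, 22 adjusted over the list alone and 11 with the covariate (mean 0.89, adjusted p = 2.91e-08, adjusted p = 0.163 with an estimated correlation). They included IFI44 at 2.75. The interferon-gamma list had 18 of 28 higher, 19 adjusted over the list alone and 7 with the covariate (mean 1.05, adjusted p = 2.91e-08, adjusted p = 0.0638 with an estimated correlation). Among them were CXCL10 at 4.61 ± 0.41 and GBP5 at 2.16. MHC class I presentation rose in 14 of 15 by both counts and in 4 with the covariate (mean 0.95, adjusted p = 2.91e-08). They included B2M at 2.51 and HLA-E at 2.15. MHC class II genes rose in 6 of 12, 7 adjusted over the list alone and 4 with the covariate (mean 0.77, adjusted p = 7.96e-05, adjusted p = 0.0638 with an estimated correlation). Among them were HLA-DRA at 3.24 ± 0.24 and CTSS at 2.02. JAK-STAT components had 7 of 16 higher and 1 lower, 8 and 1 adjusted over the list alone, and 3 higher with the covariate (mean 0.47, adjusted p = 0.0194, adjusted p = 0.132 with an estimated correlation). They included JAK2 at 1.18. IFNG gave 0.38 (adjusted p = 0.263).

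Leukocyte lists also rose in HLP. Lymphocyte chemokines had 9 of 19 higher and 1 lower, 13 and 1 adjusted over the list alone, and 6 higher with the covariate (mean 1.12, adjusted p = 3.47e-05). Among them were CCR4 at 1.74 and CCL5, a chemokine made by activated T cells, at 1.46. Macrophage genes rose in 10 of 14 by both counts and in 6 with the covariate (mean 0.72, adjusted p = 7.72e-06, adjusted p = 0.0638 with an estimated correlation). They included TYROBP at 1.65 and CD68 at 1.41 ± 0.15. T cell genes rose in 5 of 11 by both counts and in 2 with the covariate (mean 0.53, adjusted p = 0.0394, adjusted p = 0.23 with an estimated correlation). Among them were CD2 at 1.75 ± 0.21 and CD3D at 1.56. Their call was lost without control replicate 7 (0.52, adjusted p = 0.0737), control replicate 12 (0.51, adjusted p = 0.0753) or HLP replicate 8 (0.50, adjusted p = 0.0545). Cytotoxic genes rose in 4 of 14, 6 adjusted over the list alone and 2 with the covariate (mean 0.59, adjusted p = 0.0297, adjusted p = 0.205 with an estimated correlation). GZMA was higher by 2.47 ± 0.31, with 17 of 17 arrays above every control. CD4 helper genes rose in 4 of 8, 6 adjusted over the list alone and 3 with the covariate (mean 0.56, adjusted p = 0.0245, adjusted p = 0.132 with an estimated correlation). Without control replicate 7 the cytotoxic list gave 0.57 (adjusted p = 0.0692) and the CD4 list 0.55 (adjusted p = 0.0532). Checkpoints rose in 4 of 14 by both counts and in 1 with the covariate (mean 0.42, adjusted p = 0.033, adjusted p = 0.23 with an estimated correlation), and lost their call without control replicate 7 (0.41, adjusted p = 0.0693), control replicate 12 (0.41, adjusted p = 0.0563) or HLP replicate 14 (0.42, adjusted p = 0.0535).

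Matrix and gland lists changed in HLP in the same directions as in LP. Extracellular matrix genes had 15 of 26 higher and 1 lower, 17 and 1 adjusted over the list alone, and 6 higher with the covariate (mean 0.88, adjusted p = 1.23e-06, adjusted p = 0.0899 with an estimated correlation). Among them were COL6A3 at 2.45 and TNC at 2.31. Fibroblast genes rose in 6 of 12, 7 adjusted over the list alone and 2 with the covariate (mean 0.997, adjusted p = 0.000498, adjusted p = 0.225 with an estimated correlation). They included LUM at 3.21. In the narrow part of the shared range the fibroblast mean was -0.0605. Sebaceous gland genes fell in 7 of 12 by both counts and in 4 with the covariate (mean -0.59, adjusted p = 0.000695, adjusted p = 0.163 with an estimated correlation), among them THRSP, a regulator of lipid synthesis, at -1.61, the neuropeptide gene GAL at -1.11 and AWAT2 at -0.87 ± 0.21. EDC4 was lower in HLP at -2.57 and USP17L15 at -2.89 ± 0.37, and of the 166 genes at least 2-fold lower 65 were small RNAs, 48 pseudogenes and 40 protein coding.

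Other lists did not pass camera in HLP. The IL-17 and IL-36 response had 6 of 24 higher and 3 lower, 7 and 3 adjusted over the list alone, 4 and 0 with the covariate (mean 0.74, median -0.05, adjusted p = 0.308). The main camera test also did not call the type 2 response (4 higher and 1 lower, mean 0.35, adjusted p = 0.414, and 0.0147 with the covariate), lipid synthesis (6 higher and 4 lower, mean 0.21, adjusted p = 0.652) and immediate-early genes (6 higher and 1 lower, mean 0.30, adjusted p = 0.102). By fry the type 2 response (adjusted p = 0.000155) and immediate-early genes (adjusted p = 0.00433) were called higher. Ribosomal proteins gave a mean of 0.37 (adjusted p = 0.0721), mast cells 0.58 (0.0811), conventional dendritic cells 0.31 (0.164), plasmacytoid dendritic cells 0.32 (0.224), Langerhans cells 0.19 (0.741) and CD8 T and NK cells 0.31 (0.578). Sweat glands gave -0.33 (adjusted p = 0.0651), nerve -0.13 (0.185), hair follicle -0.00 (0.326), smooth muscle 0.21 (0.453), melanocytes 0.33 (0.43), adipocytes -0.02 (0.442), neutrophils 0.25 (0.985) and skeletal muscle -0.00 (0.663). For B cells (mean 0.11) and endothelial cells (mean 0.02), each at adjusted p = 0.663, mean and test differed in sign, and so did mean and median for neutrophils (median -0.01). Sweat glands passed at -0.39 to -0.38 (highest adjusted p = 0.0495) without control replicate 1, 8, 9 or 11 or HLP replicate 3, 5 or 6, and ribosomal proteins at 0.41 (adjusted p = 0.0376) without control replicate 12. With the range covariate sweat glands (-0.59, adjusted p = 0.00483), nerve (-0.24, adjusted p = 0.0205) and conventional dendritic cells (0.29, adjusted p = 0.0384) also passed.

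HLP was also compared with LP directly. Single genes did not pass, while lists of antigen presentation, chemokine and dendritic cell genes lay lower in HLP. limma called 0 of 22312 genes at adjusted p, with 1366 at an unadjusted p under 0.05, and the rank-sum test called 0, with 1477. Among the named genes, low adjusted p-values were those of CCL22, a chemokine of mature dendritic cells (-0.83 ± 0.17, adjusted p = 0.118), CD68 (-0.66 ± 0.13, adjusted p = 0.118), CD74 (-0.71 ± 0.15, adjusted p = 0.154) and CD83 (-0.73 ± 0.17, adjusted p = 0.162). SPRR2G, a cornified envelope precursor chosen after its values were seen, lay higher in HLP at 1.02 ± 0.23 (adjusted p = 0.154). CXCL9 gave -1.02 ± 0.28 (adjusted p = 0.327), POSTN 1.40 ± 0.43 (adjusted p = 0.483) and LCE3E 0.86 ± 0.30 (adjusted p = 0.586). With the range covariate CD68 was called at -0.67 ± 0.13 (adjusted p = 0.046). Without LP replicate 4, LP replicate 6 or HLP replicate 6, limma called 1, 2 and 1 genes, which were CD68 in each refit (-0.70 to -0.68) and CCL22 in 1 (-0.89, adjusted p = 0.038).

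Of the 40 lists 21 passed between HLP and LP, 16 lower in HLP and 5 higher. MHC class II presentation shifted by a mean of -0.44 (camera adjusted p = 7.94e-10) with 8 of 12 members lower adjusted over the list alone, dendritic cells by -0.35 (adjusted p = 5.31e-08) with 5 lower, chemokines by -0.37 (adjusted p = 9.74e-08) with 3 lower and the interferon-gamma list by -0.29 (adjusted p = 1.68e-08) with 3 lower. T cells shifted by -0.29 (adjusted p = 4.69e-05, 4 members lower), checkpoints by -0.25 (4.22e-05, 2 lower), CD4 helper T cells by -0.27 (0.00106, 2 lower), cytotoxic genes by -0.22 (0.000797, 2 lower), Langerhans cells by -0.35 (0.0013, 1 lower), nerve by -0.22 (0.0013, 1 lower) and JAK-STAT components by -0.16 (0.000531), all counts adjusted over the list alone. These 11 lists also passed with an estimated correlation, but within title block 1, which holds all LP arrays, the cytotoxic, JAK-STAT and nerve lists lost their calls. In the shared signal range the interferon-gamma (-0.0848, adjusted p = 0.618), cytotoxic (-0.0208), JAK-STAT (-0.0831), checkpoint (-0.14) and nerve (-0.17) lists lost theirs. The other lists lower in HLP were lost with an estimated correlation. They were interferon-stimulated genes at -0.17 (adjusted p = 0.0013, adjusted p = 0.414 with an estimated correlation), and, with the 2 p-values in the same order, MHC class I at -0.15 (0.00829, 0.286), immediate-early genes at -0.20 (0.00158, 0.217), macrophages at -0.18 (0.000309, 0.0774) and plasmacytoid dendritic cells at -0.20 (0.00799, 0.0764). MHC class I also lost its call without HLP replicate 1 (-0.11, adjusted p = 0.0542), and the interferon-stimulated genes gave -0.30 (adjusted p = 2.66e-10) without HLP replicate 5.

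The 5 lists higher in HLP than LP were lost with an estimated correlation. The cornified envelope shifted by 0.19 (adjusted p = 0.00068, adjusted p = 0.371 with an estimated correlation) and, with the 2 p-values in the same order, desmosomes by 0.16 (0.0145, 0.414), extracellular matrix by 0.15 (0.0072, 0.37), wound genes by 0.13 (0.0369, 0.414) and smooth muscle by 0.12 (0.0223, 0.338). Without LP replicate 5 the cornified envelope gave 0.12 (adjusted p = 0.0228) and desmosomes 0.09 (adjusted p = 0.128), and without HLP replicate 12 desmosomes gave 0.13 (adjusted p = 0.0569). Wound genes lost their call in 16 refits at 0.07 to 0.11 (highest adjusted p = 0.15), those without LP replicates 1, 2, 3, 5, 6, 7, 8, 14, 16 and 20 and HLP replicates 10, 12, 13, 15, 16 and 17. Smooth muscle lost its call in 5 at 0.08 to 0.10 (highest adjusted p = 0.0909), those without LP replicates 3 and 4 and HLP replicates 2, 3 and 6.

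The remaining lists did not pass between HLP and LP, at means from -0.17 for sweat glands (adjusted p = 0.594), sebaceous glands (adjusted p = 0.143) and CD8 T and NK cells (adjusted p = 0.0999) to 0.13 for mast cells (adjusted p = 0.1). Mean and test differed in sign for neutrophils (adjusted p = 0.919) and melanocytes (adjusted p = 0.971), and median and test for the type 2 response (median 0.04), lipid synthesis and adipocytes (median -0.01 each). Single left-out arrays brought CD8 T and NK cells (-0.21, adjusted p = 0.0402 without LP replicate 4), the IL-17 response (0.09, adjusted p = 0.0356 without LP replicate 15), cell cycle (-0.12, adjusted p = 0.00855 without HLP replicate 13), fibroblasts (0.14 to 0.18 without LP replicate 1, 9 or 11 or HLP replicate 15) and mast cells (0.16 to 0.17 without LP replicate 11 or HLP replicate 15 or 17) past the threshold. Within title block 1, which holds all 21 LP but only 6 HLP arrays, 12 of the 21 lists passed, and with title block as a covariate 16. Leaving out dim genes ended the plasmacytoid dendritic cell, smooth muscle and nerve calls, leaving out the least correlated arrays the desmosome call, and quantile normalization, median centring or the range covariate the wound call. In the shared signal range, with 10 LP and 6 HLP arrays, 8 of the 21 passed, MHC class I gave 0.0435 and the cornified envelope -0.025. In its narrow part, with 8 LP and 5 HLP arrays, the interferon-gamma list gave 0.0492, cytotoxic genes 0.13, macrophages 0.0901 and the cornified envelope -0.31, and within title block 1 wound genes gave -0.15.

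**Figure D3:**
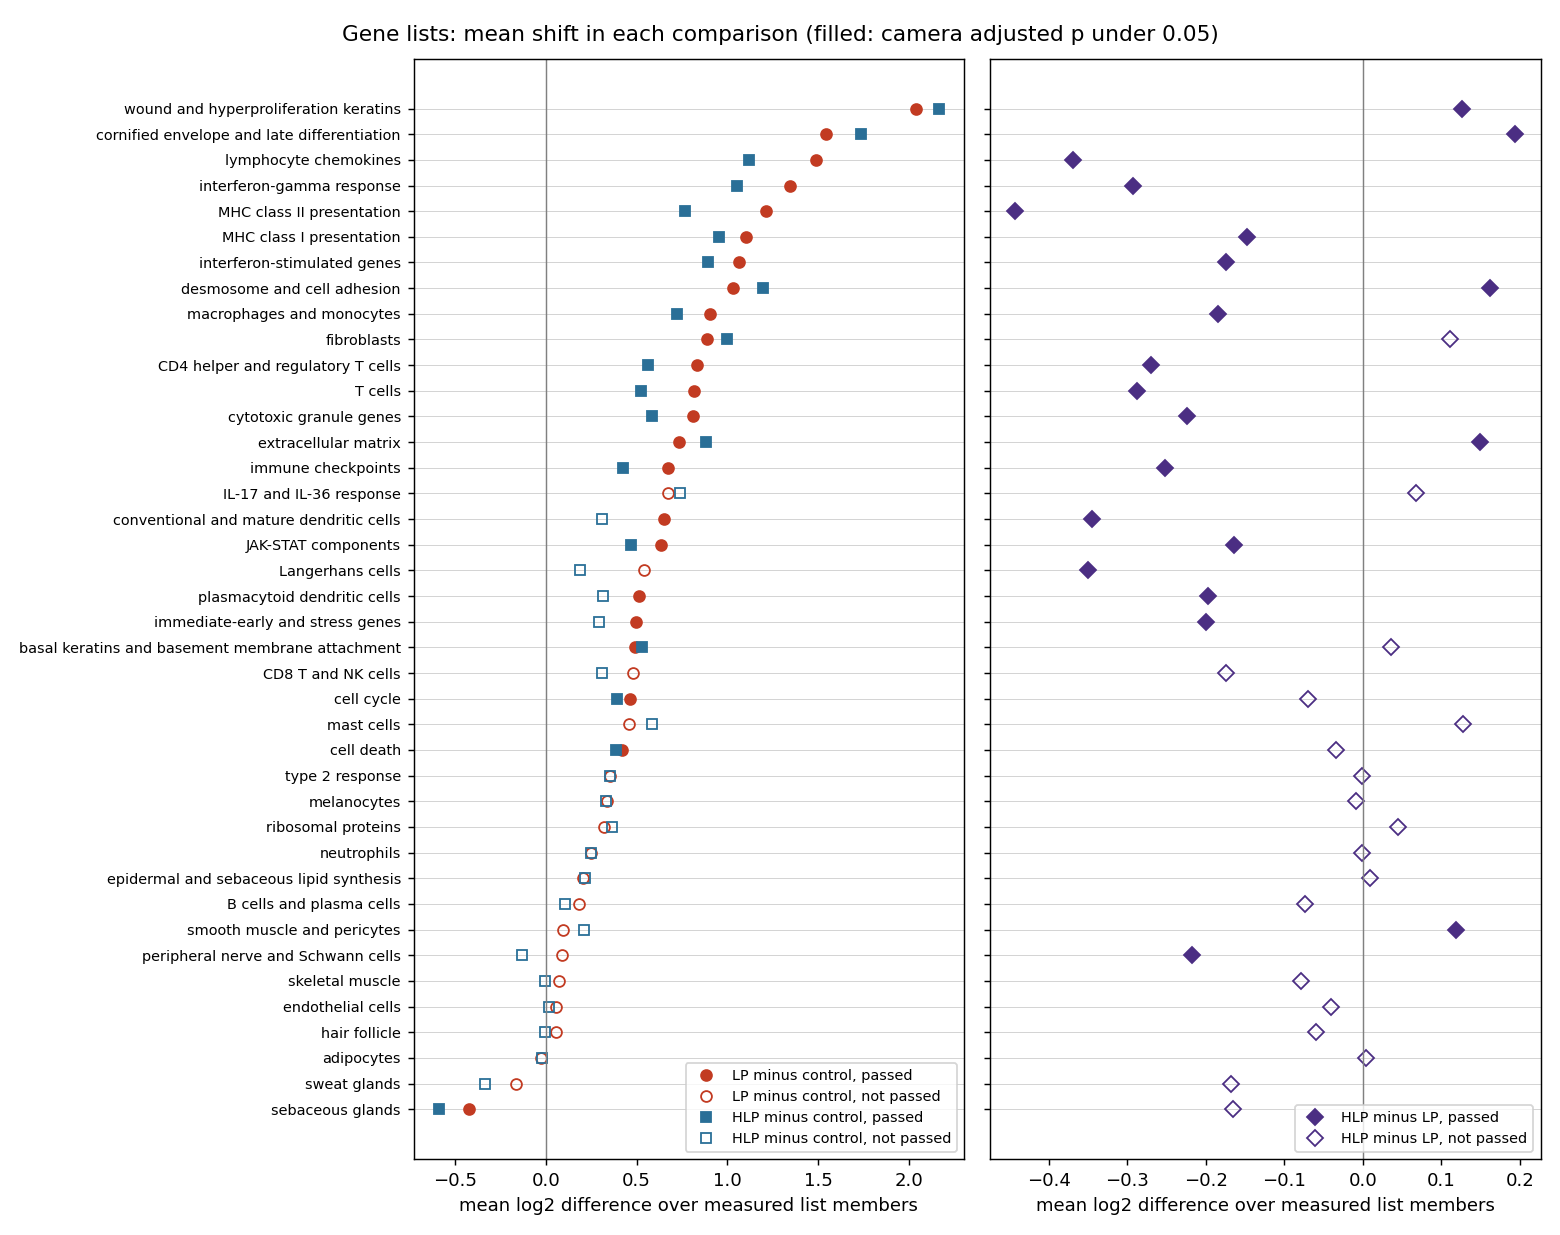
Mean log2 difference (horizontal axes) of the measured members of 40 gene lists, with LP and HLP each against control on the left and HLP against LP on the right; filled markers passed camera at adjusted p under 0.05. Wound genes stood highest against control (2.04 in LP, 2.17 in HLP), and MHC class II presentation lowest in HLP against LP (-0.44).

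Changes in LP and HLP against the same controls ran together across genes. The log2 changes correlated at r = 0.951 with a covariance of 0.265 over 22312 genes, which are not independent replicates, and 87.2% had the same sign. Unchanged groups simulated against these controls gave r = 0.658, a covariance of 0.0215 and 72.2% of the same sign. With the controls split into 6 and 6 the observed values were r = 0.813, 0.242 and 75.1%. Genes higher in both, such as CXCL9, HLA-DRA and KRT16, numbered 3825, where independent lists would share 928.8, and genes lower in both, such as EDC4 and AWAT2, 1566 against 229.6. With split controls these were 2129 against 443.6 and 319 against 63.9. Splitting the controls does not remove the difference in signal range between lesions and controls.

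**Figure D4:**
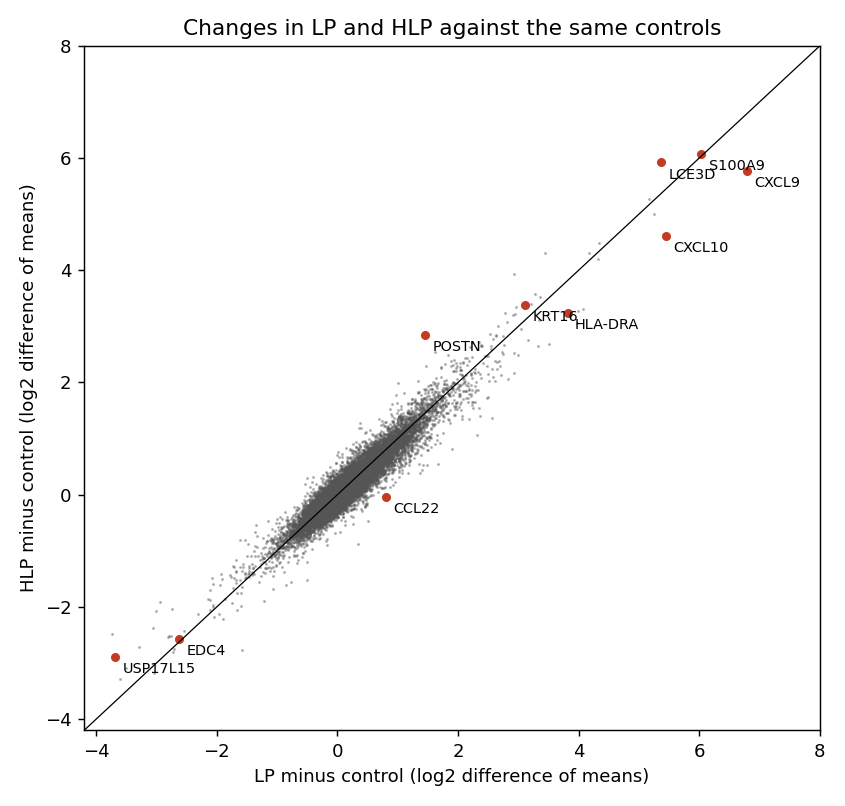
Log2 change in LP (horizontal axis) against log2 change in HLP (vertical axis), both minus control, with 1 dot per gene for 22312 genes, a line at equal change and 10 genes named. Values follow the line (r = 0.951), with POSTN above it (1.45 in LP, 2.85 in HLP) and CXCL10 under it (5.45 and 4.61).

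Scores of interferon-gamma response genes and T cell genes were then compared across arrays within each group, as 3 relations. The interferon-gamma score averaged -0.856 ± 0.138 (SD, n = 12) in control, 0.428 ± 0.338 (SD, n = 21) in LP and 0.075 ± 0.479 (SD, n = 17) in HLP, and the T cell score -0.591 ± 0.296, 0.367 ± 0.461 and -0.037 ± 0.27. No group showed a relation past the threshold. In LP r was 0.075 (permutation p = 0.75, adjusted 0.75) and rho 0.004 (p = 0.99, adjusted 0.99), in HLP r was 0.336 (p = 0.19, adjusted 0.37) and rho 0.326 (p = 0.2, adjusted 0.6), and in control r was 0.363 (p = 0.25, adjusted 0.37) and rho 0.217 (p = 0.5, adjusted 0.75). Without the 2 arrays farthest from the median T cell score r was -0.057 in LP, 0.356 in HLP and 0.651 in control (p = 0.044, adjusted 0.13). As residuals on title block r was 0.466 in HLP (p = 0.058, adjusted 0.15) and 0.493 in control (p = 0.1, adjusted 0.15), while LP lies in 1 block. With the median over list members in place of the mean, rho in control passed at 0.692 (adjusted p = 0.047).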

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

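The counts of random splits and the tests on the immune, interferon-gamma and chemokine lists by processing order, signal range and brightness were chosen after the results were seen. The predictions on signal range in LP, on processing order in HLP and on T cells were written before those tests were run. Signal range itself was taken up only after the data were seen.

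A signal appeared in probe sets outside the comparisons, those without exactly 1 gene name. Of 29746 such probe sets 2758 changed at least 2-fold in LP against control (1364 higher, 1394 lower) and 2627 in HLP (1376 higher, 1251 lower), while limma called 0 between HLP and LP, with 1477 at an unadjusted p under 0.05. Without the 2-fold limit, 7485 were called in LP (2437 higher, 5048 lower) and 6869 in HLP (2329 higher, 4540 lower). These calls ran mostly lower, while those of the named genes ran mostly higher. The probe sets stand out because the comparisons of single genes did not use them.

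Random regrouping of the arrays did not reach the counts of changed genes against controls. Such splits treat the arrays as independent, and they cannot tell disease from other differences between the groups, such as signal range. In LP 1 of 100 splits of the arrays, the real one, gave as many genes, with 7104 against at most 65 in another split, and 1574 against 10 at 2-fold. In HLP it was again 1 of 100, with 6541 against 452 and 1470 against 145. Between HLP and LP limma called 0 genes in the real split, with 1366 at an unadjusted p under 0.05 and 0 by the rank-sum test. All 100 of 100 splits gave as many, which was fixed in advance because any split calls at least 0. The highest other split gave 1 gene there, and 0 at 2-fold.

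Control arrays had a narrower range of signal than lesion arrays, while 7104 and 6541 genes changed in LP and HLP. The slope on the 95th percentile within groups gave a median of 44.0% (interval 34.6 to 53.0) of the log2 change of genes at least 2-fold higher in LP, and 6.7% (-3.3 to 27.3) of those lower. Both intervals end under the 80% set for it as the whole cause, so it may account for part of the higher calls. They cover only LP genes picked for a change of at least 2-fold, a choice that can itself lower the share. Smaller changes, and those in HLP, were not tested in this way. In HLP, of the genes called at least 2-fold higher in title block 1, 1323 of 1332 (99.3%) were higher in blocks 2 and 3, and 142 of 154 lower ones (92.2%) were lower there, which argues against processing order as the whole cause. The interferon-gamma and chemokine lists kept at least 75.7% of their mean and their calls with the range covariate in both diseases, and rose above unlisted genes of like brightness by at least 0.63 (SE 0.0921) and, where smallest against its error, 0.71 (SE 0.115). This argues against signal range or a general loss of RNA signal in healthy biopsies as the whole cause for these lists, while for the other calls RNA yield or quality stays open beside disease.

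Immune lists lay lower in HLP than LP. Within title block 1 the 256 genes of all 20 fixed immune lists, called or not, differed by -0.157, which is -2.43 SD of 1000 random draws of LP arrays, against -0.172 over all arrays. This argues against processing order as the whole cause, although of the 14 immune lists called lower 10 stayed called in title block 1, 12 with title block as a covariate and 10 with an estimated correlation. The 95th percentile averaged 3.83 in HLP and 3.81 in LP. All 14 lists stayed called with it as a covariate, the interferon-gamma mean being -0.31. This argues against a difference in mean signal range between HLP and LP as the cause. In the range shared with controls, which keeps 10 LP and 6 HLP arrays, 7 stayed called. The interferon-gamma mean went there from -0.29 to -0.0848 and cytotoxic genes from -0.22 to -0.0208. Macrophages went from -0.18 to -0.0107 and MHC class I from -0.15 to 0.0435. That setting cannot tell signal range from the choice of fewer arrays, so it does not decide for these lists. With the T cell score as a covariate the interferon-gamma score difference kept 80.3% of its size, -0.283 against -0.353, but its permutation p went from 0.012 to 0.062, so fewer T cells and a lower response in HLP cannot be told apart for this score, the spread between arrays keeping both open.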

How the results depend on the processing

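The settings on signal range and the refits without single arrays were chosen after the data were seen; the others were planned. Over all settings 575 summary values, 1636 list results and 6408 named gene results kept their direction and side of the threshold or moved by under 1.5 times. Past 1.5 times moved 31 summary values, while 138 lists and 576 named genes no longer passed, 49 and 30 newly passed, and 17 and 27 changed direction. The summary values include 9 from each refit without a single array. Those refits change the data little, so they raise the share of summary values kept. Of 131 named genes called in LP 128 kept their direction and 112 their call after quantile normalization, 131 and 90 with the range covariate. In HLP, of 122, these were 119 and 107, and 122 and 71. Leaving out dim genes moved the median of all genes from 0.008 to 0.299 in LP and from -0.008 to 0.271 in HLP. No paired analysis was possible because the labels name no donor, and the replicate numbers used here only count arrays within a group. Signal near background limits the dim genes.

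Genes changed in LP fell in number to 4031 in title block 1, 1764 with the range covariate, 2533 in the shared range and 87 in its narrow part, which has 8 LP, 5 HLP and 3 control arrays, and at 2-fold to 517, 834 and 84 in the last 3. In HLP they were 2296 in title block 1, 3767 in blocks 2 and 3, 1259, 1437 and 46, and at 2-fold 419, 702 and 46. Fewer arrays lower such counts by construction, and for the covariate the cause was not tested. Between HLP and LP the covariate called 1. With fry all 23 lists called in LP and all 20 called in HLP stayed called, and 7 and 10 more passed. The 7 in LP, all higher, were the IL-17, type 2, ribosomal, CD8, Langerhans, mast cell and melanocyte lists. In HLP the IL-17, type 2, immediate-early, ribosomal, both dendritic cell, mast cell and melanocyte lists were higher, and the sweat gland and nerve lists lower. Lists called in LP were 14 without dim genes and 12 with an estimated correlation. In HLP they were 12 in title block 1 and 3 with an estimated correlation, and of the 20 lists 12 passed without dim genes and 17 with array weights. Between HLP and LP they were 11 with an estimated correlation, 13 with fry, 9 in the shared range and 4 in its narrow part, 1 of these the cornified envelope, now lower in HLP (-0.31). The LP and HLP changes correlated at 0.909 with the covariate, 0.858 and 0.804 in the shared and narrow ranges and 0.813 with split controls, which differ by construction in their controls. With the covariate their covariance went from 0.265 to 0.138. Genes higher in both went from 3825 to 739, and genes lower in both from 1566 to 244. Leaving out each array in turn gave 6571 to 7612 genes in LP (1463 to 1853 at 2-fold, 22 to 23 lists), 5991 to 7027 in HLP (1379 to 1693, 16 to 21 lists) and 0 to 2 between them (0 to 0, 19 to 23 lists).

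Directions turned as follows, and the cause was not tested beyond the fewer arrays. An adjusted p (camera for lists, limma for genes) is given where the turned result passed. In the narrow range the basal list gave -0.0125 in LP, and fibroblasts gave -0.13 in LP and -0.0605 in HLP. Lipid synthesis gave -0.32 (adjusted p = 0.0065) in LP and -0.35 (adjusted p = 0.0102) in HLP there. Ribosomal proteins gave -0.19 (adjusted p = 0.0378) and -0.24 (adjusted p = 0.033) in the same order. Between HLP and LP, in the narrow range, interferon-stimulated genes gave -0.0106 with a turned test, interferon-gamma 0.0492 and MHC class I 0.0699 (0.0435 in the shared range). Cytotoxic genes gave 0.13 there, macrophages 0.0901 and the cornified envelope -0.31 (adjusted p = 0.00215, and -0.025 in the shared range). Hair follicle, also between HLP and LP, gave 0.24 (adjusted p = 0.0287) in the shared range and wound genes -0.15 in title block 1. After quantile normalization FLG gave -0.0273, LORICRIN -0.45 (adjusted p = 0.0136) and RPS18 -0.52 (adjusted p = 0.000344) in HLP. With that setting RPL30 gave -0.16 in LP, FSCN1 -0.18 in LP and -0.21 in HLP and RPS6 -0.0755 and -0.0789. FLG gave -0.0885 in HLP in the shared range and LHX2 0.023 in LP in title block 1. In the narrow range ACACA gave -0.14, FLG -0.59 and MYLK -0.0017 in HLP, ACTA2 -0.22 and MITF -0.0824 in LP, and in LP and HLP POSTN -0.77 and -0.51, RPL19 -0.34 and -0.49, RPS6 -0.0885 and -0.18, SFRP2 -0.16 and -0.0282, TCF4 -0.65 and -0.61 and TYMS -0.42 and -0.26.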

Other observations

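The gene families here were chosen after their values were seen, as were the tests of explanations for the sebaceous list, while the list and its own test were fixed before.

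Several gene families moved in the lesions, and part of their members also stand in the fixed lists, so they in part restate those results. Of all tested genes 21.5% were higher and 10.4% lower in LP, and 19.4% and 9.9% in HLP. Guanylate-binding protein genes, which interferon-gamma induces, rose in 6 of 6 in LP and 5 of 6 in HLP, with 5 in each after quantile normalization again and 4 in each with the range covariate. GBP1, GBP2, GBP4 and GBP5 are members of the interferon-gamma list, and outside it GBP3 was higher by 0.997 in LP and 1.37 in HLP. Cathepsin genes rose in 11 of 15 in LP and 8 of 15 in HLP (11 and 9 after quantile normalization, 6 and 4 with the covariate), including CTSC, which activates granzymes, by 2.01 in LP, and CTSS, CTSW and CTSG stand in fixed lists. Proteasome genes rose in 33 of 44 in LP and in 32 with 1 lower in HLP. After quantile normalization this was 24 higher and 2 lower in LP and 23 and 2 in HLP, and 11 higher in LP and 6 higher with 1 lower in HLP with the covariate. PSMA3, outside the lists, was higher by 2.21 in LP and 2.13 in HLP, while PSMB8, PSMB9, PSMB10, PSME1 and PSME2 are members of them.

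Of the 17 families looked at, some had few calls or went both ways. Collagen genes had 6 higher and 7 lower of 42 in LP and 8 and 9 in HLP, keratins 7 and 6 of 47 in LP and 9 and 6 in HLP, and kallikreins 2 and 2 of 14 in LP and 3 and 1 in HLP. TRIM genes had 14 higher and 4 lower of 56 in both diseases, and type I interferon genes 0 higher and 2 lower of 16. After quantile normalization collagen genes had 3 higher and 10 lower in LP and 6 and 11 in HLP, keratins 3 and 8 in LP and 4 and 7 in HLP, and kallikreins 1 and 5 in LP and 2 and 2 in HLP. With the range covariate collagens had 1 higher and 2 lower and keratins 3 and 2 in each disease. Other families had 2 to 9 members higher and 0 lower. In LP and HLP these were 4 and 5 of 5 LCE1 genes, 4 and 4 of 4 LCE2, 2 and 2 of 5 LCE3 and 4 and 5 of 11 SPRR. The S100A family had 9 and 8 of 15 higher, SERPINB 7 and 7 of 10, APOBEC3 2 and 2 of 5 and the interleukin 1 family 6 and 6 of 15. With the range covariate these were 1 to 5, S100A genes going from 9 to 4 in LP, LCE1 genes from 4 to 1 in LP and 5 to 1 in HLP, and the interleukin 1 family from 6 to 1 in both. Quantile normalization left 2 to 7 higher, with S100A genes going from 8 to 4 in HLP and the interleukin 1 family from 6 to 3 in both, and after it 1 LCE3 gene was lower in both diseases, 1 S100A gene in LP and 1 SPRR gene in HLP.

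Joining segments of the T cell receptor alpha locus had 23 of 55 higher and 1 lower in LP, and 9 higher and 1 lower in HLP. The share higher lay above the 21.5% of all tested genes in LP, but under the 19.4% in HLP. After quantile normalization this became 19 and 3 in LP and 8 and 4 in HLP, and with the range covariate 11 and 5 were higher. TRAJ21 was higher by 4.07 in LP and 3.31 in HLP, and TRAJ35 by 3.33 and 2.65. Each segment is short, and neighbouring segments can share a primary transcript. IL18, an IL-1 family cytokine of keratinocytes, was higher by 2.05 in LP and 2.22 in HLP.

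HLP was measured in all title blocks, and its change against control was compared between block 1 and blocks 2 and 3. limma called 0 genes as differing, with 1014 at an unadjusted p under 0.05, and the changes correlated at r = 0.771 across genes.

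Sebaceous gland genes fell in both diseases (mean -0.43 in LP and -0.59 in HLP, AWAT2 from 1.53 in control to 0.62 in LP), but the calls were lost with an estimated correlation (adjusted p = 0.211 and 0.163) and within title block 1, and without control replicate 7 the means were -0.26 and -0.42. AWAT2 was 4.35 in that replicate, against 0.449 to 2.22 in the other controls. Of the 12 genes measured 6 are also in the lipid synthesis list. Dilution by other cells would lower the markers of each resident skin cell type alike. The fibroblast list lay above the sebaceous list by 1.31 (SE 0.273) in LP and 1.588 (SE 0.255) in HLP. That list was itself called higher in both diseases, so it cannot test dilution. The hair follicle list lay above by 0.481 (SE 0.22) and 0.587 (SE 0.209). The sweat gland list differed by 0.26 (SE 0.319) and 0.258 (SE 0.314), within its error. With the range covariate the sweat gland list was also called lower by camera (-0.41, adjusted p = 0.0102 in LP, and -0.59, adjusted p = 0.00483 in HLP). Dilution is therefore not decided, since the hair follicle and sweat gland lists differ. Signal range as the whole cause is argued against by the call with the covariate, at a larger adjusted p of 7.3e-05. Fewer pilosebaceous units in the lesion biopsies and body site cannot be told apart, since the hair follicle list went both ways (smaller adjusted p = 0.33), and in the shared signal range gave -0.158 (adjusted p = 0.0499) in LP but 0.0801 (adjusted p = 0.812) in HLP.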
